A study of Nasonia vitripennis with 76 samples.

How the data were processed

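Polyadenylated RNA was sequenced from heads and abdomens of adult *Nasonia vitripennis*, a parasitoid wasp in which unfertilized eggs usually become haploid males and fertilized eggs diploid females. All wasps belonged to the TRA line, a line of raised ploidy that was founded by knocking down *transformer*, and were taken 1 day after emergence. The RNA was extracted without DNase treatment. The 76 libraries fall into 16 groups by sex, ploidy, generation and tissue. Females were diploid (2N) or triploid (3N) and came from generations F2 and F14, and males were haploid (1N) or diploid (2N) and came from generations F3 and F15. Each group holds 5 libraries, except the abdomens of F2 2N females and of F3 2N males, with 3 each. The labels do not say whether libraries of a group came from separate wasps, pools or rearings, so every p-value here measures only the spread between these libraries. Generation cannot be told apart from any difference between library batches, because the labels give no batch and no group spans generations.

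The expected counts per gene, as deposited, were made by the authors with STAR 2.7.11a and RSEM 1.3.1, the tools that the labels name, and their unit was read from the values, which are not all whole. TPM values of the same libraries, as deposited, were also made by the authors, and each of their columns has the sum that TPM requires. The genome build and annotation are not given in the sources used here. Counts were given for 14621 genes and TPM values for 14613, and each of the 14621 genes matched the symbol table of assembly Nvit_psr_1.1. That table was used only for names, chromosomes and gene order. Only 829 genes carry a symbol other than a LOC number. For 75 of 76 libraries the TPM column ranked genes most like the count column of the same library, and the lowest rank correlation between a library's own columns was 0.948. The TPM values were used for nothing else. RSEM shares reads among similar genes by estimation, so values of members of large families, such as odorant receptors and cytochrome P450 genes, are less certain than those of single-copy genes.

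Total counts ran from 14.2 to 60.1 M per library, with a median of 21.6 M. Expected counts were rounded to whole numbers, scaled by the TMM method and tested with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after filterByExpr had removed genes with low counts. Adjusted p-values are Benjamini-Hochberg values over all genes of a fit, and genes below 0.05 were called. Values of log2 difference are followed by their standard error. The level of a gene is its mean TMM-scaled count scaled to CPM over the libraries of a group or set of groups. Ploidy, generation and their interaction were tested in 4 fits, 1 per sex and tissue, each over its 4 groups. A ploidy difference is the higher ploidy minus the lower. All levels are relative to the library they come from, so a change of total RNA output with ploidy cannot be seen here. Generation differences are the late minus the early generation as a mean over both ploidies, and an interaction is the late ploidy difference minus the early one. Sex was compared at 2N, males minus females, as a mean over the early (F2 or F3) and late (F14 or F15) generations, which are 1 generation apart in the sexes. Tissue was compared within each sex, head minus abdomen, as a mean over 4 groups.

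The tests, the comparisons, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Genes were named by rule. For each comparison these were *Tra* and *Dsx*, the 5 called genes with the highest and the 5 with the lowest log2 difference, and up to 2 called members per gene list, taken by lowest adjusted p. The highest and lowest genes needed a level of at least 5 CPM in a compared group. For ploidy, the libraries of the compared groups could not overlap. For generation, sex and tissue, group means had to differ the same way in each pair of groups, and libraries could overlap. For interactions 3 genes were taken each way, with only the sign of the interaction of group means checked. The rule and the lists were first written on product names, which the sources do not give. They were therefore applied to symbols, with 19 lists chosen from the symbols alone before expression values were examined. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, and again with the correlation estimated, and with fry. A count of called list members adjusted over the list alone is given beside the count adjusted over all genes. Differences between ploidies were compared across genes by Pearson correlation. The median log2 level of the genes of each chromosome, relative to that of all genes, was compared by an exact permutation of library labels.

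On data simulated from the real means and library sizes, with 200 changed genes and a coefficient of variation of 0.35, the test found from 65% to 100% of genes changed by 2 log2 units and from 2% to 100% of those changed by 1 unit, depending on the comparison. At most 6.4% of calls were false. The coefficient fitted to the real libraries was higher in female heads (0.514), in heads of both sexes (0.444) and in females (0.495). It was slightly higher in female abdomens (0.37) and in abdomens of both sexes (0.369). The shares found are thus too high for those fits. Without A34 the coefficient was 0.327 in female heads, 0.331 in heads of both sexes and 0.363 in females. The lowest values were those of the interaction in female abdomens, where 2% of genes changed by 1 unit were found among 10706 tested.

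The alternatives fixed in advance were size factors by the median-of-ratios method (RLE), no filter on low counts, DESeq2 1.42.0, a fit of the compared groups only, leaving out the libraries A1A, A2A and A15A whose names carry a second letter, leaving out each library of the compared groups in turn, and a level of at least 10 CPM for the correlations, the chromosome medians and the spread. After the data were seen, fits without the library A34 of F2 3N female heads, without A34 and A35, and without the library A28 of F2 2N female abdomens were added. No library was left out of the main tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.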

Results

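RNA of 40 head and 36 abdomen libraries of the TRA line was compared by ploidy, sex, generation and tissue. Total counts per library ran from 14.2 to 60.1 M. The late heads (F14 females and F15 males) were shallower than the early ones (F2 females and F3 males), with medians of 16.9 and 21.5 M. The late abdomens had a median of 26.3 M.

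The library labelled A34 of F2 3N female heads had the profile of an abdomen. *Lop1*, a long-wavelength opsin of the eye, had 0 CPM in it and from 2346 to 19788 CPM in the other 4 libraries of its group. *oskar*, a gene needed for germ plasm in the ovary, stood at 741 CPM in A34 and at 3.52 to 24.2 CPM in the other 4. A34 correlated best with A36, an abdomen of F2 3N females (r = 0.992 across genes), and on average at 0.690 with its own group. It stays in the main tests, and values without it are given for each ploidy and interaction count in female heads and wherever they change the call of a named gene. A35 of the same group also stood apart, with the highest *Lop1* level of the group and its closest match (r = 0.952) in A2A, a head library of F3 1N males.

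**Figure D1:**
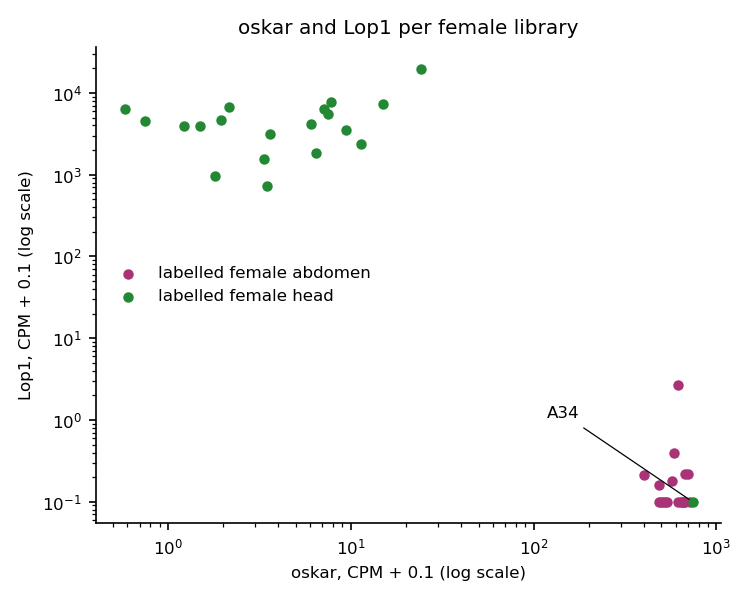
*Lop1* against *oskar* in every female library (CPM plus 0.1, log scales, 1 point per library, coloured by the tissue on the label). A34, labelled a head, lies among the abdomens with 741 CPM of *oskar* and 0 CPM of *Lop1*.

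*transformer* (*Tra*), the splicing regulator whose knockdown founded the line and which directs female development, was higher in females than in males in the head. At 2N the log2 difference of male against female heads was −2.40 ± 0.30 (adjusted p = 2.8e-07, 10 libraries against 10). Female heads of the 2N groups held 283 ± 19.7 CPM at F2 and 706 ± 83.2 CPM at F14 (SD, n = 5 each), while the mean of each of the 4 male head groups was at most 102 CPM. In female heads *Tra* rose between generations by 0.97 ± 0.34 (adjusted p = 0.025; 0.82 without A34, adjusted p = 0.00604) and in female abdomens by 1.01 ± 0.11 (adjusted p = 2.6e-05). F14 female heads had fewer genes with a count (10575 to 11644) than F2 ones other than A34 and A35 (12368 to 12641). A35 of F2, with 11366 such genes, held 1391 CPM of *Tra*. Whether the rise in heads goes with this difference between libraries was not tested. In male heads *Tra* fell by 0.71 ± 0.23 (adjusted p = 0.016), a call that ended without A1A, A2A and A15A (adjusted p = 0.285). Ploidy went with *Tra* in the abdomens of F3 males, where 2N stood 1.58 ± 0.17 above 1N (adjusted p = 4.9e-06) and each of the 3 libraries of 2N males lay above each of the 5 of 1N males. At F15 that difference was −0.20 ± 0.15 (adjusted p = 0.559), and the change between generations passed its own test (−1.77 ± 0.23, adjusted p = 8.5e-05). In F3 male heads the ploidy difference of *Tra* was −0.01 ± 0.33 (adjusted p = 0.985). It stood at 0.68 without A1A, A2A and A15A (adjusted p = 0.0166), because A1A and A2A, with 140 and 199 CPM, lay above the 52.9 to 60.7 CPM of the other 1N heads. In F2 female heads it was 0.89 ± 0.47 (adjusted p = 0.235), 1.17 ± 0.34 without A34 (adjusted p = 0.048) and 0.36 ± 0.15 without A34 and A35 (adjusted p = 0.209), since A35 alone held 1391 CPM.

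*doublesex* (*Dsx*), the transcription factor whose transcripts *Tra* splices by sex, was lower in male than in female heads (−1.11 ± 0.16, adjusted p = 2.8e-06) and higher in male than in female abdomens (2.56 ± 0.30, adjusted p = 4e-09). *fruitless* (*Fru*), which governs courtship in insects, was lower in male heads (−1.80 ± 0.19, adjusted p = 5.4e-09). *Dsx* rose between generations in male heads (0.69 ± 0.11, adjusted p = 4.8e-05) and in female abdomens (1.69 ± 0.35, adjusted p = 0.0015). In male abdomens *Dsx* stood at −0.249 (adjusted p = 0.0612), and it was called lower with RLE (−0.287, adjusted p = 0.0369) and DESeq2 (−0.287, adjusted p = 0.0227). Among the ploidy comparisons it was called in the heads of F3 males, where 2N lay 0.61 ± 0.16 below 1N (log2 difference −0.61, adjusted p = 0.015), with an adjusted p of 0.0539 when A4 of the 1N heads was left out. In F14 female heads the difference of *Dsx* was −0.59 (adjusted p = 0.589), and it passed without A34 and A35 (−0.59, adjusted p = 0.0245).

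**Figure D2:**
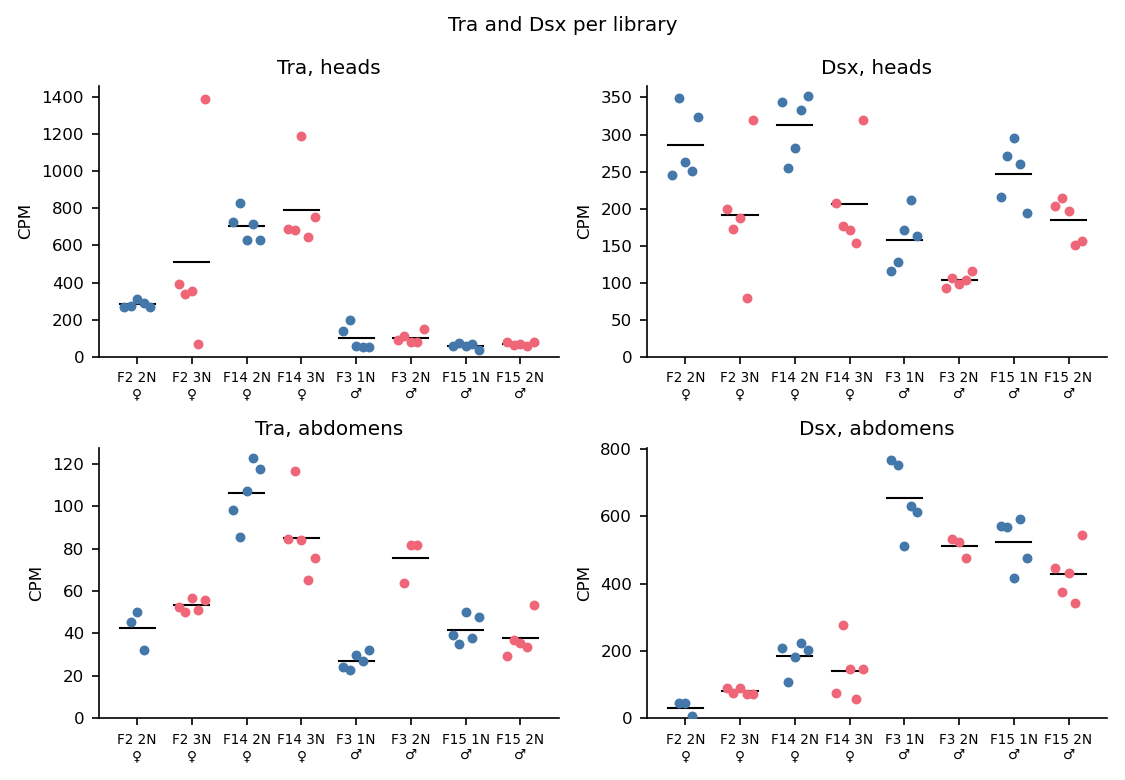
*Tra* and *Dsx* in every library (CPM, linear axes, 1 point per library, bars at group means, heads above and abdomens below). *Tra* in F3 male abdomens is higher at 2N than at 1N, and in heads A35 of F2 3N females is the highest library with 1391 CPM.

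Heads and abdomens differed in most tested genes. In females 5364 genes were higher in the head and 5328 in the abdomen, and in males 5026 and 4923. With DESeq2 these were 6104 and 4761 in females, and in males the larger side turned with RLE (4698 and 5209) and DESeq2 (4863 and 5346). Among the genes far higher in the head were an eye opsin and a neuronal peptide. *Lop1* was higher in the head by 15.93 ± 1.07 in females and 14.05 ± 0.59 in males, and *Pdf*, the peptide of clock neurons, by 10.27 ± 0.63 and 9.46 ± 0.28. Of 27 tested neuronal receptor, channel and peptide genes, 26 were higher in female heads and 22 in male heads, with adjusted p = 0.39 and 0.13 for the list at an estimated correlation (camera, 4.4e-07 and 1.6e-06 at the preset one). Subunits of oxidative phosphorylation were also higher in the head, 57 of 62 in females and 58 of 64 in males (estimated correlation, adjusted p = 0.39 and 0.65). Genes of the cell cycle, DNA repair and germ cells were on the abdomen side in females. The mitotic cyclin *cycB* differed by −8.89 ± 0.88 and *nanos*, a regulator of germ cells, by −8.88 ± 0.81, and all 16 cell cycle genes and 14 of 16 DNA repair genes were lower in the female head (estimated correlation, adjusted p = 0.39 for both lists). A34 makes the differences of *cycB* and *nanos* smaller. F2 3N female heads held 155.7 and 17.23 CPM of them with A34, and 2.23 and 1.06 CPM without it. On the abdomen side in males were detoxification genes, 53 of 72 lower in the head and 17 higher (estimated correlation, adjusted p = 0.52), and serine proteases, 27 of 39 lower and 7 higher (0.37), with *SP50* at −10.27 ± 0.53. RLE size factors moved the median difference of all genes upward by 0.172 in the female tissue comparison and by 0.195 in the comparison of male with female abdomens, and by at most 0.068 either way in the others.

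Sex was compared at 2N to hold ploidy equal. In abdomens 5627 genes were higher in males and 4890 in females. Germ line genes were lower in males: *nanos* by −12.54 ± 0.50 (86.4 CPM in females) and *oskar* by −8.31 ± 0.38. All 16 cell cycle genes, 5 of 5 germ line genes, 5 of 5 chromatin genes and 13 of 15 DNA repair genes were lower in male abdomens (estimated correlation, adjusted p = 0.12, 0.12, 0.19 and 0.18). Detoxification genes went the other way, 53 of 71 higher in males and 10 lower (estimated correlation, adjusted p = 0.34), led by the cytochrome P450 gene *CYP4AB14* (11.09 ± 0.69, 1459 against 0.653 CPM). Neuronal genes (24 of 27 higher, 1 lower), cuticle genes (19 of 30 higher, 3 lower; estimated correlation, adjusted p = 0.34 for both lists) and storage proteins (4 of 4) were higher in males as well. As a mean over both periods *Tra* was lower in male abdomens by −0.37 ± 0.13 (adjusted p = 0.011), a call lost with RLE size factors (adjusted p = 0.23) and DESeq2 (0.261). The periods went opposite ways. *Tra* stood at 75.8 CPM in F3 males against 42.6 CPM in F2 females, and at 37.8 CPM in F15 males against 106 CPM in F14 females.

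In heads 1394 genes were higher in males and 827 in females. *CYP9AG7*, a cytochrome P450 gene, reached 5007 CPM in males and 0.0591 CPM in females (17.28 ± 0.81), and *CYP4AB14* (5.85 ± 0.46) and *CYP6CK8* (6.38 ± 0.62) were higher in males too. Detoxification genes were higher in males for 24 of 68 members and lower for 5 (estimated correlation, adjusted p = 0.78). As a mean over both periods, oxidative phosphorylation genes were lower in male heads for 22 of 63 and higher for 1 (27 lower when adjusted over the list alone; estimated correlation, adjusted p = 0.78). Their summed level went opposite ways in the periods. It was 20740 CPM in F3 2N males against 16500 CPM in F2 2N females, and 16820 CPM in F15 2N males against 36380 CPM in F14 2N females. *apd-3*, an apidermin of the cuticle (−4.85 ± 0.65), and the antimicrobial peptide *Def1-1* (−3.25 ± 0.87) were lower in males. The total of 2221 called genes rose to 3995 without A34, to 4384 without A34 and A35, and to 4948 in a fit of the compared groups only.

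**Figure D3:**
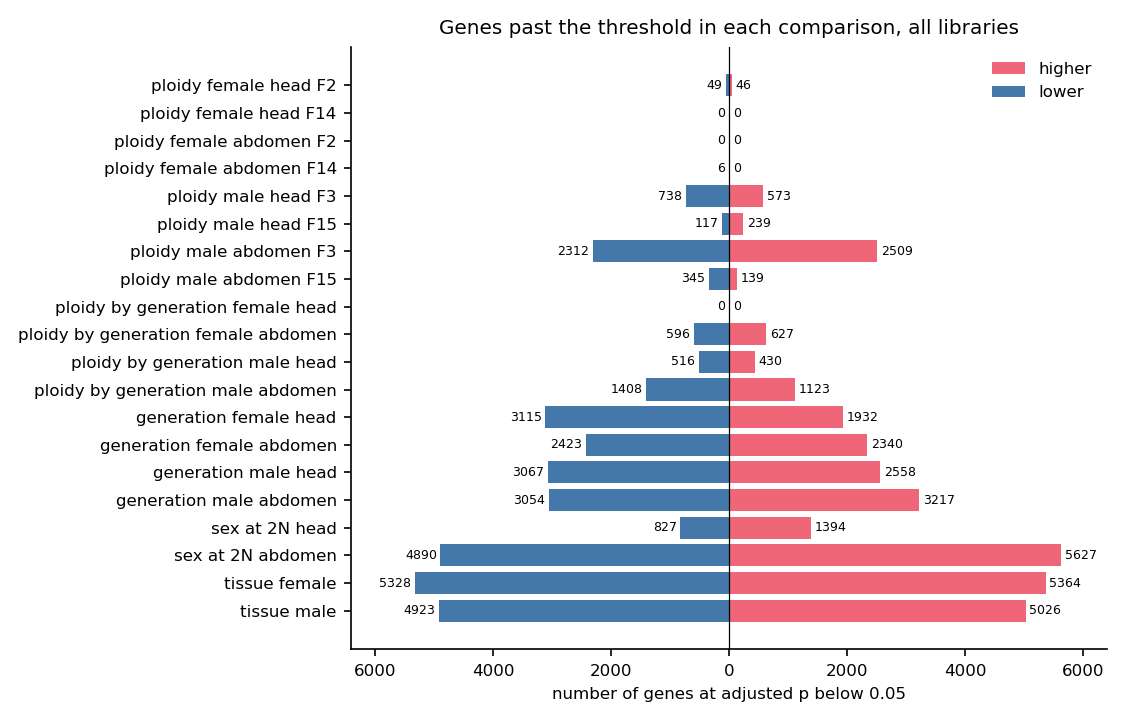
Number of genes past an adjusted p of 0.05 in each comparison with all libraries (bars to the right, higher in the group named first: higher ploidy, late generation, male or head; bars to the left, lower). Each tissue and generation comparison calls at least 4763 genes, while ploidy calls from 0 in 2 female comparisons to 4821 in F3 male abdomens.

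Between generations F2 and F14 female heads changed in 5047 genes, 1932 higher and 3115 lower at F14. Odorant receptor genes fell together: 105 of 131 tested were lower and 1 higher (107 lower when adjusted over the list alone), with adjusted p = 6e-19 by camera and 0.51 with an estimated correlation. Without A34, 124 of 143 were lower, and *Or1* fell by 5.24 ± 0.72, from 258 to 8.71 CPM. Detoxification genes also fell, 42 of 63 lower against 6 higher (estimated correlation, adjusted p = 0.37), led by *CYP6AQ8* (−8.34 ± 1.26, 9.13 against 1144 CPM) and the carboxylesterase *CCE-B6* (−8.24 ± 1.58). Subunits of oxidative phosphorylation rose for 59 of 62 members, *Uqcr10* by 1.91 ± 0.16 (adjusted p = 5.5e-27 by camera, 0.37 with an estimated correlation). The antimicrobial peptide *Def1-2* rose by 3.85 ± 0.53 (to 415 CPM), and the cuticle genes *CPR37* and *apd-3* by 6.95 ± 0.57 and 4.84 ± 0.73, while the 24 tested cuticle genes split into 5 higher and 4 lower. The muscle gene *Tm1*, a tropomyosin, rose by 1.63 ± 0.23. *Dnmt1a*, a maintenance DNA methyltransferase, fell by 1.43 ± 0.31 and the histone deacetylase *Rpd3* by 2.12 ± 0.43, and 4 of 5 chromatin genes were lower. Without A34, the fall of *Dnmt1a* was 0.98 ± 0.16 and that of *Rpd3* 1.46 ± 0.25 (log2 differences −0.98 and −1.46). The summed level of the odorant receptors varied within groups: A34 and A35 held 16.7 and 28.9 CPM against 291 to 766 CPM in the other F2 female heads, and F14 female heads held 30.8 to 120 CPM.

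**Figure D4:**
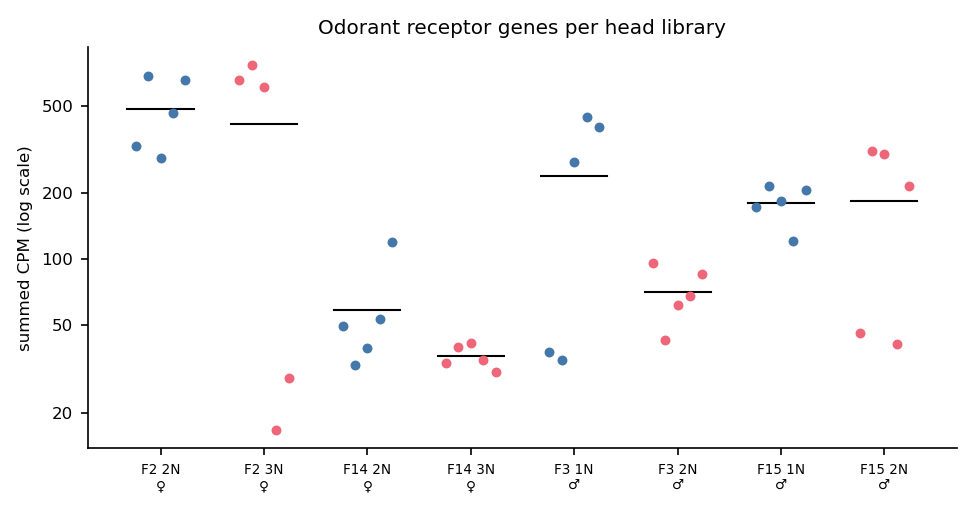
Summed CPM of the odorant receptor genes tested in heads (log scale, 1 point per library, bars at group means). All 10 F14 female heads lie at or below 120 CPM, while the F2 2N female heads start at 291 CPM and F3 1N male heads range from 34.8 to 445 CPM.

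Male heads changed in 5625 genes between F3 and F15, 2558 higher and 3067 lower at F15. Here detoxification genes rose, 34 of 66 higher and 9 lower (adjusted p = 3.3e-05 by camera, 0.55 with an estimated correlation), led by *CYP6AQ4* (3.14 ± 0.27, 1339 against 164 CPM). Oxidative phosphorylation genes fell for 45 of 63 members and rose for 2 (2.5e-08 by camera, 0.55 with an estimated correlation), *Atp5o* by 1.21 ± 0.13 (log2 difference −1.21). Cuticle genes *CPR37* (−4.79 ± 0.48) and *CPR48* (−3.16 ± 0.57, 887 against 8889 CPM) fell, as did *apd-3* (−4.24 ± 0.49), while of the 25 tested cuticle genes 6 were higher and 8 lower. Serine proteases were higher for 14 of 29 and lower for 5, *SP76* by 6.30 ± 1.27 and *SPH103* by 3.36 ± 0.27. Among 25 neuronal genes 13 were lower and 4 higher, *nAChRa10*, a subunit of the nicotinic acetylcholine receptor, at −1.37 ± 0.12 and the chloride channel subunit *LCCH3* at −0.99 ± 0.09.

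In female abdomens 2340 genes were higher and 2423 lower at F14 than at F2 (2526 and 2236 with RLE, 2971 and 2343 with DESeq2). Of these, 1376 were at least 2-fold higher and 146 at least 2-fold lower. Cuticle genes rose, 16 of 23 with none lower (7.8e-05 by camera, 0.30 with an estimated correlation), and so did nerve genes, 9 of 23 with none lower (0.00068 and 0.34). *Syt1*, the calcium sensor of synaptic vesicles, rose by 1.29 ± 0.21 and *Para*, the voltage-gated sodium channel, by 1.44 ± 0.27. Genes of DNA repair and recombination fell for 9 of 15 members with none higher (7.8e-05 and 0.30), *Hop2*, which acts in meiotic pairing, by −1.18 ± 0.18. Cell cycle genes fell for 8 of 16, *Cdk2* by −0.83 ± 0.15 (0.021 and 0.63). The cyclin *cycB* fell by 0.70 ± 0.24 (log2 difference −0.70, adjusted p = 0.0245), while *oskar* differed by −0.18 ± 0.09 (adjusted p = 0.125) and *nanos* by −0.24 ± 0.13 (adjusted p = 0.143), short of the threshold. *Tm1* rose by 0.76 ± 0.12, and 2 of 3 muscle genes were higher.

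Male abdomens changed in 6271 genes, 3217 higher and 3054 lower at F15 (3028 and 3241 with RLE, 3183 and 3448 with DESeq2). Detoxification genes rose for 36 of 71 members and fell for 11 (0.018 by camera, 0.58 with an estimated correlation), led by *CYP4AB15* (5.64 ± 1.22) and *CYP336B1* (3.46 ± 0.26, 266 against 25.4 CPM). Oxidative phosphorylation genes fell for 38 of 64 with none higher (1.1e-06 and 0.58), *Atp5j* by −1.25 ± 0.15. Chromatin genes rose for 4 of 5 (0.028 and 0.58), *Rpd3* by 1.77 ± 0.19. *CPR37* fell by 3.20 ± 0.38 (log2 difference −3.20), and royal jelly-like *Mrjpl3* rose by 2.55 ± 0.23. The counts of all 4 generation comparisons stayed within 1.5 times under every alternative.

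Among the ploidy comparisons the most genes were called in the abdomens of F3 males, where 2N and 1N differed in 4821 genes, 2509 higher and 2312 lower at 2N (3 libraries against 5). The larger side turned with RLE (2223 higher, 2513 lower) and DESeq2 (2411 and 2837). Among the higher were the carboxylesterase *CCE-A4* (3.92 ± 0.54, 70.7 against 4.65 CPM), *CYP4G44*, of the P450 family that makes cuticular hydrocarbons (2.63 ± 0.30, 805 against 130 CPM), the royal jelly-like *Mrjpl5* (2.42 ± 0.22), the adipokinetic hormone receptor *Akhr* (2.08 ± 0.35, 211 against 49.9 CPM) and the ribosomal protein *Rpl7a* (0.98 ± 0.18). Lower were *Cox7a1*, a subunit of cytochrome c oxidase (−3.19 ± 0.80), *Uqcrc2*, of the cytochrome bc1 complex (−1.03 ± 0.16), *Brd8* (−1.19 ± 0.18) and *Dnmt1a* (−0.87 ± 0.16). Cell cycle genes were lower for 7 of 16 and higher for 1 (8 lower when adjusted over the list alone; adjusted p = 0.031 by camera, 0.52 with an estimated correlation), and chromatin genes were lower for 4 of 5 and higher for 1 (0.038 and 0.52). Oxidative phosphorylation genes were lower for 17 of 64 and higher for 3 (0.031 and 0.95). Detoxification genes went both ways, 14 of 71 higher and 12 lower. When each of the 8 compared libraries was left out in turn, the count lay between 3540 and 4688.

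Heads of F3 males differed by ploidy in 1311 genes, 573 higher and 738 lower at 2N. *Cpap3-e*, a cuticle protein (2.69 ± 0.42), *CYP6CK7* (2.41 ± 0.44) and *CYP6AQ5* (1.65 ± 0.27) were higher. Lower were *apd-3* (−4.24 ± 0.67, 9.07 against 170 CPM), the cuticle protein *CPR22* (−2.79 ± 0.54) and *Y-e*, of the yellow family that acts in pigment formation (−2.49 ± 0.46, 47.5 against 268 CPM). Oxidative phosphorylation genes were lower for 20 of 63 members with none higher (34 when adjusted over the list alone; 2.9e-13 by camera, 0.72 with an estimated correlation), *Ndufs1* by −0.64 ± 0.14. Odorant receptors were lower for 20 of 90 and higher for 1 (39 lower when adjusted over the list alone; 2.3e-07 and 0.72). Their summed level varied within both groups, from 34.8 to 445 CPM in 1N and from 42.9 to 96.1 CPM in 2N heads. Without A2A 2032 genes were called, without A3 796, without A4 846, without A12 824, without A1A, A2A and A15A 3665, and in a fit of these groups only 687.

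With all 4 groups fitted, fewer genes were called by ploidy at F15 than at F3. Heads of 2N and 1N males differed in 356 genes, 239 higher and 117 lower at 2N. Neuronal genes were on the higher side: *Dop2*, a dopamine receptor, by 0.81 ± 0.15 (adjusted p = 0.0065), and *pHCl*, a chloride channel, by 0.55 ± 0.12 (adjusted p = 0.018, above 0.05 without A81, A83 or A84, at 0.0535, 0.0587 and 0.067). Of 25 tested neuronal genes 3 were called, all higher (5 when adjusted over the list alone), and the list passed camera both at the preset (adjusted p = 0.00013) and at the estimated correlation (0.044). Yellow and royal jelly-like genes passed both as well, downward (0.00078 and 0.044), with 1 of 14 called (4 when adjusted over the list alone). The P450 genes *CYP6CK6* (−2.38 ± 0.40) and *CYP336B1* (−0.70 ± 0.12) were lower. The count was 117 without A81, 148 without A83, 142 without A84, 194 without A85, 220 without A72, 671 with DESeq2 (350 higher, 321 lower) and 804 in a fit of these groups only, where the F3 heads had 687.

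Abdomens of F15 males differed in 484 genes, 139 higher and 345 lower at 2N. Higher was *nAChRb3*, a nicotinic receptor subunit (2.04 ± 0.43, adjusted p = 0.014, 17.3 against 4.22 CPM), and lower were the cuticle gene *TWDL1* (−1.52 ± 0.32, adjusted p = 0.012) and *Cox6c* (−3.92 ± 0.77, adjusted p = 0.0095, 0.153 against 2.59 CPM). In a fit of these groups only, with 52 genes called, the adjusted p of these genes was 0.0942, 0.0866 and 0.0818. The count was 944 with DESeq2, 285 without A77 or A86, 315 without A80 and 309 without A90. Oxidative phosphorylation genes, with a median of 0.21, passed camera upward (2.4e-06, 0.79 with an estimated correlation) although 1 of 64 was called, *Cox6c*, which was lower.

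The ploidy difference itself changed between generations in males. In heads the interaction passed for 946 genes, 430 upward and 516 downward. For 3 detoxification genes that were called higher at 2N in F3 and lower at 2N in F15, the change was large: *CYP6CK6* had an interaction of −6.37 ± 0.63 (adjusted p = 1.9e-05), *CYP6CK7* of −3.86 ± 0.59 and *CCE-A8* of −3.83 ± 0.61. Of the 66 tested detoxification genes 9 went down and 1 up (0.00048 by camera, 0.76 with an estimated correlation). *nAChRa12* went the other way (1.09 ± 0.21), with 4 of 25 neuronal genes upward (8 when adjusted over the list alone; 0.0056 by camera, 0.42 with an estimated correlation). The count was 604 without A3, 627 without A12, 592 without A83 and 2706 without A1A, A2A and A15A. In abdomens 2531 genes passed, 1123 upward and 1408 downward (1283 and 1248 with RLE, 1600 and 1495 with DESeq2). *CYP4BW5* (3.05 ± 0.46) and *Uqcrc2* (1.12 ± 0.21) went up, with 15 of 64 oxidative phosphorylation genes (3.8e-06 by camera, 0.99 with an estimated correlation) and 4 of 5 chromatin genes, among them *Rpd3* (2.12 ± 0.37). *CCE-A4* (−4.41 ± 0.71) and *Mrjpl5* (−2.60 ± 0.30) went down.

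Heads of F2 females differed by ploidy in 95 genes with all libraries, 46 higher and 49 lower at 3N, and in 639 without A34, 399 higher and 240 lower. The genes given here come from the fit without A34, which was chosen after seeing the data. *NV_30029* was higher by 1.57 ± 0.29, the yellow-family gene *Y-x1c* by 1.32 ± 0.22 and the glutathione transferase *GstO1* by 0.64 ± 0.11 at 3N. *Tudor-sn* (−0.63 ± 0.10), the calcium-activated potassium channel *Slo* (−1.25 ± 0.29) and *CYP6AQ5* (−1.85 ± 0.45) were lower. *Or163* had no count in any 3N head of this fit against 7.60 CPM at 2N. These 7 genes were also called without both A34 and A35, where 711 passed. Oxidative phosphorylation genes were higher for 12 of 62 (44 when adjusted over the list alone; 3.5e-16 by camera, 0.72 with an estimated correlation), and for 5 of 62 without both libraries. With all libraries DESeq2 called 882 genes (640 higher, 242 lower), the test with no filter 48 and a fit of these groups only 9. Each library left out moved the count: without A21 it was 22, without A22 or A23 15, without A24 37, without A25 6, without A31 979, without A32 689, without A33 1012 and without A35 158.

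At F14, female heads showed 0 ploidy genes by edgeR with all libraries, with 899 at an unadjusted p below 0.05 and 139 by DESeq2 (72 higher, 67 lower). A fit of these groups only called 196, the fit without A34 called 392 (262 higher, 130 lower) and that without both A34 and A35 1306. In the fit without A34, cuticle proteins *CPR35* (−1.66 ± 0.33) and *CPR16* (−1.22 ± 0.31), the receptor *Akhr* (−1.41 ± 0.25) and *CYP4AB15* (−4.11 ± 0.99, 1.52 against 26.2 CPM) were lower at 3N. *Mbd*, a methyl-CpG binding protein, was higher (0.49 ± 0.13), as was *Beat-ic* (0.39 ± 0.08). The cuticle list was lower for 3 of 25 members (9 when adjusted over the list alone) and passed camera at both the preset (9.6e-07) and the estimated correlation (0.046), the latter with an adjusted p of 0.17 when A35 was left out too. Leaving out A64 gave 2 genes and A55 44.

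The interaction of ploidy and generation in female heads had 0 genes by edgeR with all libraries, with 1878 at an unadjusted p below 0.05 and 406 by DESeq2 (137 upward, 269 downward). It had 711 without A34 and 1197 without both A34 and A35, 62 without A35, 38 without A55 and 2 without A62 or A64. In the fit without A34, 44 of 62 oxidative phosphorylation genes went down from F2 to F14 (57 when adjusted over the list alone; 1.6e-28 by camera, 0.27 with an estimated correlation), *Uqcr10* by −1.09 ± 0.21. *Akhr* (−1.77 ± 0.36) and *CPLCP2* (−2.28 ± 0.51) went down, and *pHCl* (0.56 ± 0.10) went up.

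In female abdomens ploidy went with few called genes, in relative levels, when all libraries were kept. At F2, 0 genes passed in edgeR, with 1635 at an unadjusted p below 0.05, 383 by DESeq2 (242 higher, 141 lower), 3 in a fit of these groups only and 83 without A28. A28 stood apart from the other F2 2N abdomens, with 1917 CPM of *cycB* against 966 and 916 and 6.27 CPM of *Dsx* against 44.4 and 44.7. At F14, 6 genes were lower at 3N and 0 higher, among them LOC100119490 (−4.10 ± 0.71) and LOC100123932 (−2.85 ± 0.48), which carry no other name. DESeq2 called 622 (111 higher, 511 lower), the test with no filter 0, a fit of these groups only 20 and the fit without A28 290 (27 higher, 263 lower). Leaving out A57 of the 3N abdomens gave 2716 genes, A67 of the 2N ones 846, A58 3 and each of the other 7 libraries 0. A57 held 285 CPM of *cycB* and 41.1 CPM of *nanos*, below the 730 to 1414 and 69.9 to 96.4 CPM of the other F14 3N abdomens. *Tra* differed by −0.27 (adjusted p = 0.227), and by −0.40 without A57 (adjusted p = 0.0364). Among 23 neuronal genes 0 were called by edgeR (6 lower when adjusted over the list alone), and camera gave adjusted p = 6.4e-06, or 0.40 with an estimated correlation.

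Between F2 and F14 the ploidy difference of female abdomens changed for 1223 genes, 627 upward and 596 downward. The antimicrobial peptide *Def1-2* (−5.65 ± 1.24), the P450 gene *CYP9AG4* (−4.19 ± 0.90) and the serine protease *SP50* (−4.82 ± 1.11) went down, and the replication protein *RPA2* (0.71 ± 0.16) went up, each with an adjusted p of at most 0.0246. Neuronal genes went down for 5 of 23 (12 when adjusted over the list alone; 2.5e-06 by camera, 0.40 with an estimated correlation), and serine proteases for 10 of 39 with 1 upward (0.00021 and 0.40). This count rested on single libraries. It was 0 without A27, where these 4 genes had an adjusted p of 0.0571, and 239 without A28, 238 without A36, 263 without A37, 211 without A38, 348 without A39 or A56, 231 without A66, 531 without A68, 197 without A69, 746 without A59, 2164 without A67 and 3550 without A57. Without A57 the interaction also passed for *Tra* (−0.68, adjusted p = 0.0169) and *Dsx* (−2.04, adjusted p = 0.0276), which with all libraries stood at −0.55 (adjusted p = 0.102) and −1.65 (0.105). It was 454 with no filter and 2025 by DESeq2 (764 upward, 1261 downward), and with RLE size factors 903 genes passed, 365 upward and 538 downward.

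Across genes, ploidy differences went together in some pairs of comparisons and not in others, described here by Pearson correlations over genes, which are not independent replicates. In F3 males heads and abdomens went together (r = 0.402 over all genes tested in both): 267 genes were higher at 2N in both where 128.9 would overlap by chance, and 280 were lower in both where 131.4 would. Heads and abdomens correlated at 0.079 in F15 males, at −0.134 in F2 females (0.093 without A34) and at −0.026 in F14 females. In male abdomens F3 and F15 correlated at 0.287, with 223 genes lower in both against 67.8 by chance and 55 higher in both against 29.6. In male heads F3 and F15 correlated at 0.028, and 21 genes were higher at F3 and lower at F15 against 6.1 by chance, 10 lower and then higher against 16.1, 12 lower in both against 7.9 and 3 higher in both against 12.5. In female abdomens the differences at F2 and F14 ran opposite (r = −0.364), and in female heads they correlated at 0.030 (−0.047 without A34). The correlation in female abdomens was not computed without A28 or A57, which stood apart from their groups, so single libraries may set its sign. Females and males correlated at 0.177 in early heads (0.098 without A34), 0.026 in early abdomens, 0.081 in late heads and 0.096 in late abdomens.

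In 8 ploidy comparisons over 5 chromosomes, 0 of 40 differences in chromosome medians passed an exact permutation test (two-sided, Benjamini-Hochberg), also with 0 passing for genes of at least 10 CPM. The differences ran from −0.02 to 0.02 log2 units and the lowest adjusted p was 0.286, with 5 of 40 at an unadjusted p below 0.05. The smallest p the exact test can give is 0.00794 for 5 libraries against 5 and 0.0179 for 3 against 5, so 1 chromosome alone could not go below an adjusted p of 0.317, and the count of 0 does not rule out a shift. The median spread of a gene between libraries of a group was 0.29 log2 units (SD) in the median group. It ran from 0.17 in abdomens of F2 3N females to 0.91 in heads of F2 3N females, the latter being 0.38 without A34.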

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

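The tests of explanations for A34, for the odorant receptors and for the genes shared by F3 male heads and abdomens were chosen after these results were seen, while the search for libraries apart from their group and the interaction tests were planned. Chance sets a library apart in about 1 of 20 groups, and 7 of 64 tests did so here.

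A34, labelled as a head of F2 3N females, had a mean correlation of 0.690 with its group. Its mean correlation with the 5 abdomens of F2 3N females was 0.99, within the range of those abdomens among themselves (lowest 0.988), and its highest correlation with a head was 0.733. A mixture of head and abdomen RNA is argued against by 208 genes at least 100-fold higher in heads, which kept a median of −0.0984% of their head level in A34 (quartiles −0.222% to −0.0175%, after the abdomen level was subtracted). An exchange with another library of the series is argued against by 0 of 36 abdomens having their best match among the heads other than A34 (that of A40 was A34 itself). A wrong tissue label, or an abdomen taken in place of a head, may explain the profile, and no biological explanation was tested.

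Odorant receptor genes were lower in F14 than in F2 female heads, and A65, with a summed 120 CPM, lay above the other F14 2N heads. Lower depth is argued against: with the F2 heads other than A34 and A35 thinned to 15.9 M, the median log2 difference over 96 receptor genes was −4.05 (quartiles −5.17 to −3.05). These genes were chosen for reaching 1 CPM in the thinned F2 heads, so the size of the fall is partly set by that choice. A candidate explanation is that receptor-bearing tissue was kept in some head libraries and lost in others, since 3 of 6 head groups outside the F14 females held libraries whose sums differed by more than 3 times (26.5 times in F2 3N females without A34, 12.8 in F3 1N males and 7.55 in F15 2N males). A change between generations cannot be told apart from it, because 1 F2 head, A35 with 28.9 CPM, was as low as an F14 one. For some libraries low sums went with a wider difference. On the first principal component of heads (31.5% of variance over 2000 genes), A35, A1A and A2A stood at −44.11, −35.19 and −45.1. F14 female heads ran from −85.8 to −46.34 and F2 2N ones from 35.97 to 45.49. A81 and A84 of F15 2N males, also low (46.2 and 41.3 CPM), stood at 24.26 and 29.29. Whether other genes called between F2 and F14 female heads share this difference was not tested.

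In F3 males, 42 genes were at least 4-fold apart between 2N and 1N with no overlap of libraries in both tissues. Of these, 25 were higher and 17 lower at 2N, where 1.51 and 1.80 would be shared by chance, and no overlap arises by chance for 0.794% of genes in heads and 3.57% in abdomens. LOC100678671 was higher by 6.60 in heads and 7.97 in abdomens, and LOC100679420 was lower (−4.36 and −7.61). Ploidy as such is argued against, since 12 of the 42 differed at least 2-fold the same way in either tissue at F15 (LOC100678671 by −0.46 and −0.26, LOC100679420 by 0.48 and −0.37). The 42 genes held 3 pairs of neighbours in gene order, where 95% of 10000 random sets held at most 1 and the highest held 4. Linked stretches of sequence that differed between families of the 2 ploidies may contribute, though the labels give no families. Reads shared between neighbouring copies stay open too, and the pairs cannot tell apart the causes of a shared change between neighbours.

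*Tra* stood at 1391 CPM in A35, above the other F2 3N female heads (338 to 394 CPM without A34), and at 1188 CPM in A53, above the other F14 3N female heads (645 to 755 CPM). The mean correlation with the own group was low for A24 of F2 2N female heads (0.975), A15A of F3 2N male heads (0.962) and A75 of F15 1N male heads (0.970). A24 also held more of genes that were far higher in female abdomens. It had 23.2 CPM of *cycB* against 0.4 to 1.83 CPM in the other F2 2N heads, and 14.9 CPM of *oskar* against 5.92 to 7.66 CPM. The cause was not tested. The ploidy difference changed between generations, by the interaction term, for 1223 genes in female abdomens, 946 in male heads and 2531 in male abdomens. In 1, 4 and 1 of 100 splits of the libraries, the real one included, as many genes passed. The highest counts of the other splits were 72, 4437 and 1896. These splits exchanged libraries between generations within each ploidy. The generation difference was thus not kept and could enter the interaction of another split, so the splits cannot decide about chance. The count in female abdomens was 0 without A27. The 4437 genes of another split may hold the generation difference of male heads, which alone had 5625 genes.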

How the results depend on the processing

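Fits without A34, without A34 and A35 and without A28 were added after seeing the data, and the other alternatives were planned. No paired analysis was possible because the labels do not link libraries of separate groups to the same wasp or family. RLE size factors kept all 20 counts of called genes within 1.5 times, and the 4 generation, 2 tissue and abdominal sex counts stayed so under every alternative run. Of 483 called genes chosen for naming, 389 kept their call in each of the alternatives set in advance and 436 in each alternative that used all libraries. Of the 483, 7 lost their call with RLE, 23 with no filter and 10 with DESeq2, as did 18 of 159 in fits of the compared groups only, 6 of 153 without A1A, A2A and A15A and 16 of 60 without A28.

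With no filter, the ploidy count was 48 in F2 female heads and 0 in F14 female abdomens, and the interaction in female abdomens 454. DESeq2 gave 882 and 139 ploidy genes in F2 and F14 female heads, 383 and 622 in F2 and F14 female abdomens, 671 in F15 male heads and 944 in F15 male abdomens, with interactions of 406 in female heads and 2025 in female abdomens. A fit of the compared groups only gave 9 and 196 ploidy genes in F2 and F14 female heads, 3 and 20 in F2 and F14 female abdomens, 687 and 804 in F3 and F15 male heads, 52 in F15 male abdomens and 4948 for sex in heads. Without A1A, A2A and A15A, F3 male heads had 3665 ploidy genes and 2706 for the interaction, and the difference of *Tra* there turned from −0.01 to 0.68 (0.682, adjusted p = 0.0166). Without A34 there were 639 and 392 ploidy genes in F2 and F14 female heads, 711 for the interaction and 3995 for sex in heads. Without A34 and A35 these were 711, 1306, 1197 and 4384. Without A28 female abdomens had 83 and 290 ploidy genes at F2 and F14 and 239 for the interaction. Apart from the loss of samples, the cause was not tested.

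Of 248 list tests, 96 passed camera at the preset correlation, 2 with the correlation estimated and 89 by fry (56 shared with camera). Over genes of at least 10 CPM, correlations moved from −0.364 to −0.554 (female abdomens, F2 and F14), from 0.287 to 0.401 (male abdomens, F3 and F15), from 0.402 to 0.526 (F3 male heads and abdomens) and from 0.081 to 0.218 (late heads of the sexes). Without A34, F2 female heads and abdomens moved from −0.134 to 0.093.

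Leaving out 1 library of the compared groups at a time gave these ranges, which do not cover libraries of other groups in the same fit, such as A34 for F14 female heads (392) and for sex in heads (3995). Female heads had 6 to 1012 ploidy genes at F2, 0 to 44 at F14, 0 to 711 for the interaction and 4673 to 6607 for generation. Female abdomens had 0 to 83, 0 to 2716, 0 to 3550 and 3939 to 5076. Male heads had 796 to 2032 at F3, 117 to 333 at F15, 592 to 1351 for the interaction and 5257 to 5800 for generation, and male abdomens 3540 to 4688, 285 to 673, 1808 to 2742 and 5846 to 6673. Sex gave 1949 to 2137 in heads and 10415 to 10498 in abdomens, and tissue 10627 to 10774 in females and 9828 to 9993 in males. Single genes chosen for naming lost their call in 488 of 9921 cases.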

Other observations

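The split counts for ploidy in F2 and F14 female heads, and for F2 female heads without A34, were chosen after the result was seen, and the other split counts were planned.

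Yellow and royal jelly-like genes leaned downward at 3N in F14 female abdomens, with a median of −1.86 and 9 of 15 lower when adjusted over the list alone, although 0 passed over all genes (edgeR; camera adjusted p = 0.00016, 0.4 with an estimated correlation). Their ploidy difference changed between generations for 4 of 15 downward and 1 upward (9 and 1 when adjusted over the list alone), and 12 of 16 were higher in male than in female abdomens with 2 lower. Gustatory receptor genes were higher in male abdomens for 11 of 12 (camera adjusted p = 0.044, 0.26 with an estimated correlation) and odorant receptor genes for 40 of 64 with 6 lower (0.026 and 0.19). In heads, as a mean over both periods, 17 of 146 odorant receptor genes were lower in males and 2 higher (6.4e-08 and 0.86). The summed level of the whole list went opposite ways in the periods. It was 70.5 CPM in F3 2N males against 479 CPM in F2 2N females, and 185 CPM in F15 2N males against 60.9 CPM in F14 2N females. In female heads 4 of 8 gustatory receptor genes and 4 of 8 immunity genes rose from F2 to F14, the latter with 1 lower. Storage protein and lipid droplet genes were higher at 2N in F3 male abdomens for 3 of 4. All 4 cytosolic ribosome genes were lower in female and in male heads than in abdomens.

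*Lop1* stood at 727 to 1853 CPM in 4 of the 5 heads of F14 3N females and at 6288 CPM in A55, against 3909 to 6644 CPM in F14 2N heads. In F3 male heads it reached 11674 CPM in A1A, 16040 CPM in A2A and 9232 CPM in A15A, above the 3108 to 6098 CPM of the other libraries of both ploidies. The 3 libraries also held the highest *Tra* levels of those heads, from 140 to 199 CPM. A35 of F2 3N female heads was the highest of its group for both genes.

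Of the splits of the libraries into groups of the same sizes, 1 of 100 gave as many ploidy genes as the real one in F2 female heads (95, highest other 21; without A34 639 and 38), F15 male heads (356, highest other 4) and F15 male abdomens (484, highest other 423). In F3 male abdomens it was 1 of 56 (4821, highest other 340), in F3 male heads 3 of 100 (1311, highest other 3232) and in F14 female abdomens 4 of 100 (6, highest other 573). The limit was 5% of the splits, not adjusted for the number of comparisons. At this limit chance can be excluded, for these libraries, in F15 male heads and F3 male abdomens. F2 female heads and F15 male abdomens also lay below it, but fits of these groups only called far fewer genes. Leaving out 1 library gave 6 to 1012 genes in F2 female heads. In F15 male abdomens it gave 285 to 673, and another split gave 423. The splits alone thus do not settle chance in these groups. F3 male heads and F14 female abdomens met the limit narrowly, with larger counts in another split, so chance stays open there. The count of F14 female abdomens was 0 with no filter and without any one of 7 of the 10 libraries. A count of 0 is matched by every split, which decides nothing about chance for ploidy in F14 female heads (0 genes, 100 of 100 splits, highest other 29), ploidy in F2 female abdomens (0 genes, 56 of 56 splits, highest other 4) and the interaction in female heads (0 genes, 100 of 100 splits, highest other 1583). These edgeR counts of 0 stand beside 899, 1635 and 1878 genes at an unadjusted p below 0.05 and 139, 383 and 406 by DESeq2. The highest counts of other splits in F3 male heads and F14 female abdomens exceed the real ones and point to a structure of the libraries besides the groups. For the female head interaction the generation difference, which its splits did not keep, can give such a count. For generation, sex and tissue 1 of 100 splits gave as many genes each, so chance can be excluded: generation in female heads (5047, highest other 356), female abdomens (4763, 2492), male heads (5625, 3062) and male abdomens (6271, 1320), sex in heads (2221, 3) and abdomens (10517, 9857), tissue in females (10692, 1296) and males (9949, 5555).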
